A study of Mus musculus with 12 samples.

How the data were processed

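Total RNA of mouse male germ cells was measured on Affymetrix 3' expression arrays, 12 in all, with a single biotin label. The 4 groups of 3 arrays were primordial germ cells (PGC) of male genital ridge at E12.5, PGC-like cells (PGCLC) at day 6 of in vitro differentiation, round spermatids (RS) from testis at 3 weeks, and spermatid-like cells (SLC) made in vitro. The labels call the samples biological replicates and say that the cells were collected by FACS, without naming the gate. Groups were taken from the sample titles, and the replicate numbers in the titles did not pair arrays between groups.

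The authors deposited linear intensity values per probe set, and the only tool that the labels name is MAS5, without a version. The deposited values had a 2% trimmed mean of 499.8 to 499.9 on every array, so each array had been scaled to a common level, with no log and no quantile normalization. Detection calls, scan dates and background settings were not given. The number of arrays limits the precision of each value.

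The authors' scaling was kept. Values under the 25th percentile of the whole table, 30.8 intensity units, were set to it before the log2 transformation. Of 45101 probe sets, the 64 control probe sets were left out, as were 932 with several gene symbols and 9160 with none. Symbols were checked by Entrez identifier for 34741 probe sets. A probe set was kept if it lay above the median of the table, 92.0 units, on at least 3 arrays, whatever their group, which kept 28983 probe sets. Each gene was represented by its probe set with the highest mean, giving 14197 genes, of which 6293 had several probe sets.

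All 12 arrays entered a single limma fit (limma 3.58.1 in R 4.3.3) with 4 group means, lmFit and eBayes with an intensity trend. Each gene had a single variance over the 4 groups, so spread among the PGCLC arrays enters the SE and p of every contrast. The 5 contrasts were PGCLC minus PGC, SLC minus RS, SLC minus PGCLC, RS minus PGC, and the interaction, which is the SLC minus PGCLC change less the RS minus PGC change. P values were adjusted by Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05 with a change of at least 2-fold. Folds come from differences of mean log2 values, so they differ from ratios of the mean signals printed. A fold is written "at least" where an array of the lower group lay at the floor and the ratio of mean signals was no smaller. Where that ratio was smaller both are given, without a bound. The order of folds that involve the floor is not settled. Folds of the interaction are fitted values and no bounds. Where a text gives "rose" or "fell", the gene was called.

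The comparisons, the 18 gene lists, the rule for naming genes and 28 alternative settings, counting each array left out, were fixed before the data were examined. The lists were pluripotency, early PGC, gonadal germ cell, DNA methylation machinery, epiblast and mesoderm, fetal gonad somatic, blood and endothelium, meiotic prophase, late meiosis, acrosome, sperm chromatin and tail proteins, axoneme, spermatogonia, testis somatic, proliferation, stress and immediate early, imprinted, and sex-linked check genes. The 472 X-linked genes were treated as a further list. Members without a probe set of their own or under the filter were not measured, among them Nanos3, Amh, Insl3 and H19. Each list was tested with limma camera at a preset correlation of 0.01 and again with the estimated correlation between genes, adjusting over the lists within a contrast. It was also tested with fry, whose p values were not adjusted. The estimated correlation of a list was the same in every contrast, so it takes in the spread of the PGCLC arrays throughout. Counts of called members are given over all genes tested and with p adjusted over the list alone.

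The genes named were the 5 largest rises and the 5 largest falls among called genes whose arrays did not overlap between the groups, leaving out symbols that are only clone or model names, and the 2 members with the largest absolute change in each list assigned to the comparison, called or not. For the interaction only the first part applied. The landmark genes were named in advance as well. Any other gene was named after its values were seen.

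RNA quality was read from the log2 ratio of 3' to 5' control probe sets for Gapdh and Actb and from the labelling and hybridization spikes, with two-sided exact permutation tests of 3 against 3 arrays, which cannot give a p under 0.1. The fit was tested on simulated data made by moving 200 of 14197 genes by 1.5 or 2 on the log2 scale in arrays of 1 group. In 5 draws it recovered 74.8% and 82.8% of them for PGCLC minus PGC and 78.4% and 84.0% for SLC minus RS, with 0 in the wrong direction and a mean of 55 and 14.6 false calls. In the same draws, fits of the 6 arrays compared recovered 56.4% and 69.8% for PGCLC minus PGC, with a mean of 14.4 false calls. Beside 200 moved genes, each of these means is a larger share of the calls than the adjusted p threshold allows. For SLC minus PGCLC the 12-array fit recovered 73.4% and 81.6%, with a mean of 58 false calls. The excess was largest for these 58 and for the 55 of PGCLC minus PGC, so adjusted p values of both contrasts may be too small. The simulated noise had the SD of each group, mostly larger in PGCLCs, while this fit has a single variance per gene. Fits of the 6 arrays compared left 14.4 for PGCLC minus PGC and 18 for SLC minus PGCLC, still above what the threshold allows. The cause of that remainder was not tested.

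The alternatives covered between-array scaling, the floor, the filter, the choice of probe set, the variance prior, array weights, fits of the 2 groups compared alone, the replicate number as a block, the fold threshold, and leaving out each array in turn. A further 2 were chosen after seeing the data, namely keeping only PGCLC replicate 1 and raising the SLC arrays by 0.78 on the log2 scale. Python 3.11.15 with matplotlib 3.10.9 drew the plots. Chromosomes came from the array's annotation table, and no genome build or finer position was used.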

Results

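The series measured mRNA levels in male mouse germ cells at 2 stages, each taken from the animal and made in culture, on 12 arrays. PGCs, the embryonic precursors of sperm, were collected at E12.5, and PGCLCs, their in vitro counterparts, at day 6. RS are the haploid cells that follow meiosis, and SLCs are the in vitro cells that the labels set beside them. Each group had 3 arrays. Array medians lay between 73.2 and 107 intensity units, and 44.5% to 53.0% of probe sets were above the filter level on each array. Signals below are means ± SD of 3 arrays.

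Landmark genes separated the stages. Pou5f1, a core pluripotency factor, was at 6918 ± 151 in PGCs and 6468 ± 520 in PGCLCs, against 188 ± 27.4 in RS and 84.8 ± 16.01 in SLCs. Nanog, another pluripotency factor, was at 2920 ± 131 in PGCs and 7126 ± 3710 in PGCLCs and at the floor on all RS and SLC arrays. Prdm1, a PGC specification factor, was at 2268 ± 113, 1174 ± 702, 52.0 ± 27.5 and 244 ± 29.5 in PGCs, PGCLCs, RS and SLCs. Dppa3 was at 21480 ± 585 in PGCs and 11400 ± 7811 in PGCLCs, and near the floor in RS and SLCs. Nanos3 was not measured.

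The germ cell RNA-binding genes were bright at both stages. Ddx4 was at 7327 ± 341 in PGCs, 3410 ± 3015 in PGCLCs, 11380 ± 439 in RS and 7461 ± 601 in SLCs. Dazl was at 20010 ± 1744, 10000 ± 7481, 2456 ± 148 and 1344 ± 50.2 in the same order. Of the meiotic genes, Stra8 was at 157 ± 93.2, 166 ± 37.4, 499.5 ± 69.5 and 290.2 ± 20.01, Sycp3 at 2996 ± 201, 1645 ± 904, 4341 ± 438 and 2544 ± 64.4, and Dmc1 at 314 ± 3.43, 268 ± 61.1, 271 ± 60.7 and 187.5 ± 12.7. The acrosome genes Acr and Acrv1 reached 4737 ± 360 and 11660 ± 871 in RS and 1908 ± 238 and 7475 ± 283 in SLCs. Prm1 and Tnp1, which encode proteins that replace histones in sperm, were at 24260 ± 1608 and 31110 ± 1976 in RS and at 20560 ± 340.4 and 24960 ± 723 in SLCs, and near or under the floor in PGCs and PGCLCs.

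**Figure D1:**
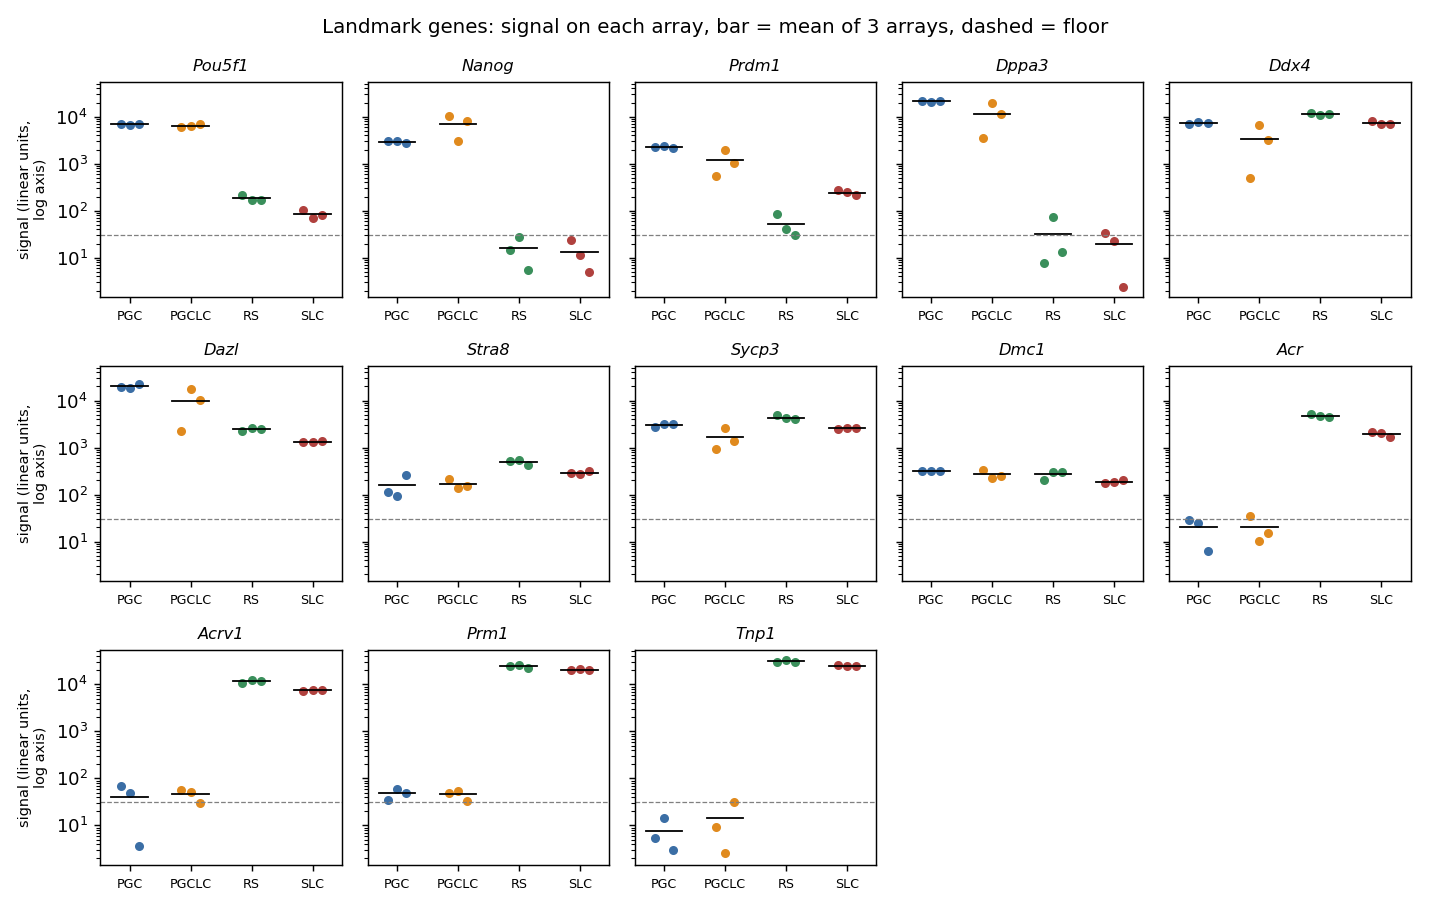
Signal of 13 landmark genes on each of the 12 arrays, in linear intensity units on a log axis. Points are arrays, bars are group means and the dashed line is the floor of 30.8 units. Prm1 and Tnp1 average 24260 and 31110 units in RS and 20560 and 24960 in SLCs, and the PGCLC points of Ddx4 and Dppa3 spread from 485.6 to 6507 and from 3567 to 19190.

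Arrays of a group resembled each other most in PGCs, RS and SLCs. Across genes, which are not independent replicates, Pearson's r between arrays was 0.986 to 0.988 within PGCs, 0.976 to 0.984 within RS and 0.984 to 0.987 within SLCs. Within PGCLCs it was 0.914 to 0.976, and between PGC and PGCLC arrays 0.884 to 0.974. PGCLC replicate 2 correlated with the PGC arrays at 0.973 to 0.974 and with PGCLC replicate 1 at 0.914, so the PGCLC group mean averages unlike arrays. The median SD between replicates on the log2 scale was 0.24 in PGCLCs against 0.08 in PGCs, 0.09 in RS and 0.08 in SLCs. RS and SLC arrays correlated at 0.779 to 0.790, and RS and PGC arrays at 0.269 to 0.278.

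The PGCLC arrays differed from each other in named genes. The germ cell gene Ddx4 was at 485.6 units on replicate 1, 6507 on replicate 2 and 3237 on replicate 3. Nanog was at 10150, 2985 and 8247 in the same order, and Zic1, a transcription factor of neural development, at 2790, 206.6 and 2094. Embryonic globin Hbb-y was at 1136, 15000 and 7843, beside 11650 ± 408 in PGCs. Most of the 20 measured fetal gonad somatic genes were likewise lowest on replicate 1 and highest on replicate 2, with Nr5a1, a regulator of steroidogenic genes, at 10.1, 416 and 167 units beside 145 ± 38.2 in PGCs. The collagen gene Col3a1 was at 1280, 4250 and 2370 beside 1650 ± 173. Dlk1, at 1170, 570 and 1060, and Col1a1, at 326, 397 and 293, did not follow that order. Over the 20 genes, the median log2 difference from PGCs was -1.44 on PGCLC replicate 1 and 1.39 on replicate 2. Hbb-y was named by the rule in another comparison, and Nr5a1, Col3a1, Dlk1 and Col1a1 were chosen here after their values were seen.

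PGCLCs were compared with PGCs to ask how the in vitro cells differ from fetal germ cells. Stress and immediate early genes were higher in PGCLCs, with 18 of 20 rising, among them Fos and Jun, and so were imprinted genes, with 15 of 22 rising, among them Igf2, a fetal growth factor. Genes of the gonadal germ cell program were lower, with 10 of 19 falling, and 11 of 26 meiotic prophase genes fell. With an estimated correlation between genes none of these lists passed limma camera (adjusted p = 0.294 for stress, imprinted and meiotic prophase and 0.319 for gonadal germ cell). By fry, which does not compare members with other genes, the unadjusted p was 8.29e-05 for stress and 8.97e-05 for imprinted. It was 0.00122 for meiotic prophase and 0.00838 for gonadal germ cell by fry. A fit of the 6 PGC and PGCLC arrays alone kept 171 of the 1685 calls, among them 3 imprinted rises, 1 meiotic prophase fall and 0 gonadal germ cell genes, and the stress list was not counted in that fit. On PGCLC replicates 1, 2 and 3 the median log2 signal was 10.86, 9.09 and 10.28 for the stress list, beside 8.07 to 8.31 in PGCs, and 11.43, 9.81 and 10.76 for the imprinted list, beside 8.88 to 9.10. It was 8.11, 10.82 and 9.59 for the gonadal germ cell list, beside 11.13 to 11.23, and 7.91, 9.06 and 8.31 for the meiotic prophase list, beside 9.25 to 9.52. Igf2 rose 6.81-fold, from 1147 ± 54.9 units in PGCs to 9216 ± 5389 in PGCLCs (log2 2.77, SE 0.43, limma adjusted p = 0.00206). Afp, which encodes a fetal plasma protein, fell at least 5.94-fold, from 183 ± 9.73 to the floor on all PGCLC arrays (log2 -2.57, SE 0.25, limma adjusted p = 0.000173).

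Of 14197 genes, 1458 were higher and 227 lower in PGCLCs, which is 11.9% of the genes tested. In the simulation this comparison made more false calls than the adjusted p threshold allows, so its adjusted p values may be too small. The largest fitted rises were those of Cldn4, a tight junction gene, from 33.9 ± 17.9 to 2490 ± 1900 units (at least 43.6-fold, log2 5.45, SE 0.71, adjusted p = 0.000897), and of the transcription factor Klf9, from 75.9 ± 9.80 to 3875 ± 2831 (36.5-fold). Zic1 rose at least 34.6-fold from the floor to 1697 ± 1337. Fabp3, a fatty acid carrier, and Socs3, an inhibitor of cytokine signalling, each rose 32.4-fold, to 8069 ± 6473 and 2973 ± 1846. The largest fitted falls were those of Tbx4, a T-box factor (6.09-fold on the log2 scale and 3.03-fold by mean signals, 1357 ± 38.5 to 447.9 ± 458, adjusted p = 0.0471), Rasd2 (6.00-fold, and 3.17-fold by mean signals, adjusted p = 0.0394), Afp, the calcium channel gene Cacna1f (5.64-fold, 559 ± 31.6 to 112 ± 68.6) and Brdt, a bromodomain gene of the testis (5.11-fold, and 2.79-fold by mean signals, adjusted p = 0.043).

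Of 22 pluripotency genes, 8 rose and 0 fell, also adjusted over the list alone. Tbx3 rose at least 27.6-fold to 1292 ± 964 and Tdgf1, a Nodal co-receptor, 7.64-fold to 6212 ± 4730. Of 16 early PGC genes, Rhox6, an X-linked homeobox gene, rose 2.53-fold, and Dnd1, required for PGC survival, and the chemokine receptor gene Cxcr4 fell (Dnd1 by 2.92-fold). Adjusted over the list alone, 1 rose and 3 fell. Of 19 gonadal germ cell genes 10 fell over all genes and 14 adjusted over the list alone. Asz1, of the piRNA pathway, fell 3.93-fold (2296 ± 93.6 to 904.8 ± 837), while Tdrd5 did not pass (log2 -2.11, adjusted p = 0.0598). Of the meiotic prophase list, Tex12 and Sycp2, which encode synaptonemal complex proteins, fell 4.64-fold and 4.38-fold. That list had 11 falls adjusted over the list alone as well.

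In the DNA methylation list 3 of 12 rose, Dnmt3b and its cofactor gene Dnmt3l (at least 6.26-fold) and Tet2 (3.77-fold), which encodes an enzyme that oxidizes methylcytosine. Among 15 epiblast and mesoderm genes Hand1, Snai1, Wnt3a and Hoxb2 rose, the last by at least 9.44-fold to 352 ± 232, and Wnt3 fell, while Lhx1 did not pass (log2 -1.79, adjusted p = 0.0817). The macrophage genes Csf1r (6.85-fold) and Cd68 (5.03-fold) rose with Adgre1 among 14 blood and endothelium genes, and Pecam1 fell. In the fetal gonad somatic list 3 of 20 rose, Col1a1, Maf and Dlk1 (3.81-fold), while Tcf21 did not pass (log2 -1.59, adjusted p = 0.217). Of 22 imprinted genes the largest rise was Phlda2, at least 15.2-fold to 1584 ± 1341. Ccnd1, a G1 cyclin gene, rose 2.89-fold as the single call among 25 proliferation genes, and Ccnd3 was under 2-fold (log2 0.56). Adjusted over the list alone, the counts of these lists were the same, except that 1 imprinted gene was also lower.

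Testis somatic genes had 7 rises of 21, among them Acta2 and Vim. The median log2 signal of that list was 6.89, 9.76 and 8.51 on PGCLC replicates 1, 2 and 3, beside 8.09 to 8.58 in PGCs. The other lists held few calls, with 2 higher (Dkkl1, Insl6) and 3 lower (Brdt, Hspa4l, Piwil1) of 21 late meiosis genes and 1 higher (Dnah8) and 2 lower (Dnaic1, Rsph1) of 24 axoneme genes. Of 22 spermatogonia genes Gfra1 and Itga6 rose and Dmrt1, Sohlh2 and Uchl1 fell, of 24 acrosome genes Spaca1 fell, and of 7 sex-linked check genes Usp9y fell. None of the 27 sperm chromatin and tail genes was called by limma, and at an unadjusted p under 0.05 there were 2 higher and 3 lower. Adjusted over the list alone, these counts were the same apart from 0 lower acrosome genes and 2 lower sex-linked genes. X-linked genes had a median log2 change of 0.15 against 0.002 for autosomal genes, with 80 of 472 higher and 10 lower (adjusted p = 0.319 by limma camera with an estimated correlation). For the acrosome and sperm chromatin lists the sign of camera, down, differed from that of the means, 0.02 and 0.04, and for DNA methylation the median of -0.04 differed from the mean of 0.51. By limma camera the stress (median 1.91, adjusted p = 9.38e-09), imprinted (1.85, 1.03e-08), gonadal germ cell (-1.42, 6.64e-07) and meiotic prophase lists (-0.84, 3.28e-06) were among 9 of 19 lists that passed, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.294.

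A fit of the 6 PGC and PGCLC arrays alone called 168 genes higher and 7 lower and kept 171 of the 1685 calls, and of the assigned lists only meiotic prophase, with 1 fall, and imprinted, with 3 rises, still held called members. The number lower was 97, 113 and 112 without PGC replicates 1, 2 and 3 and 58, 757 and 88 without PGCLC replicates 1, 2 and 3, the number higher was 958 without PGCLC replicate 3, and with only PGCLC replicate 1 kept, an alternative chosen after seeing the data, 2294 were higher and 1225 lower, with 11 of 20 fetal gonad somatic genes lower. Median centring moved the median of all genes from 0.006 to -0.21 and the share of calls that were higher from 86.5% to 62.8%, and quantile normalization moved that share to 73.5%.

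**Figure D2:**
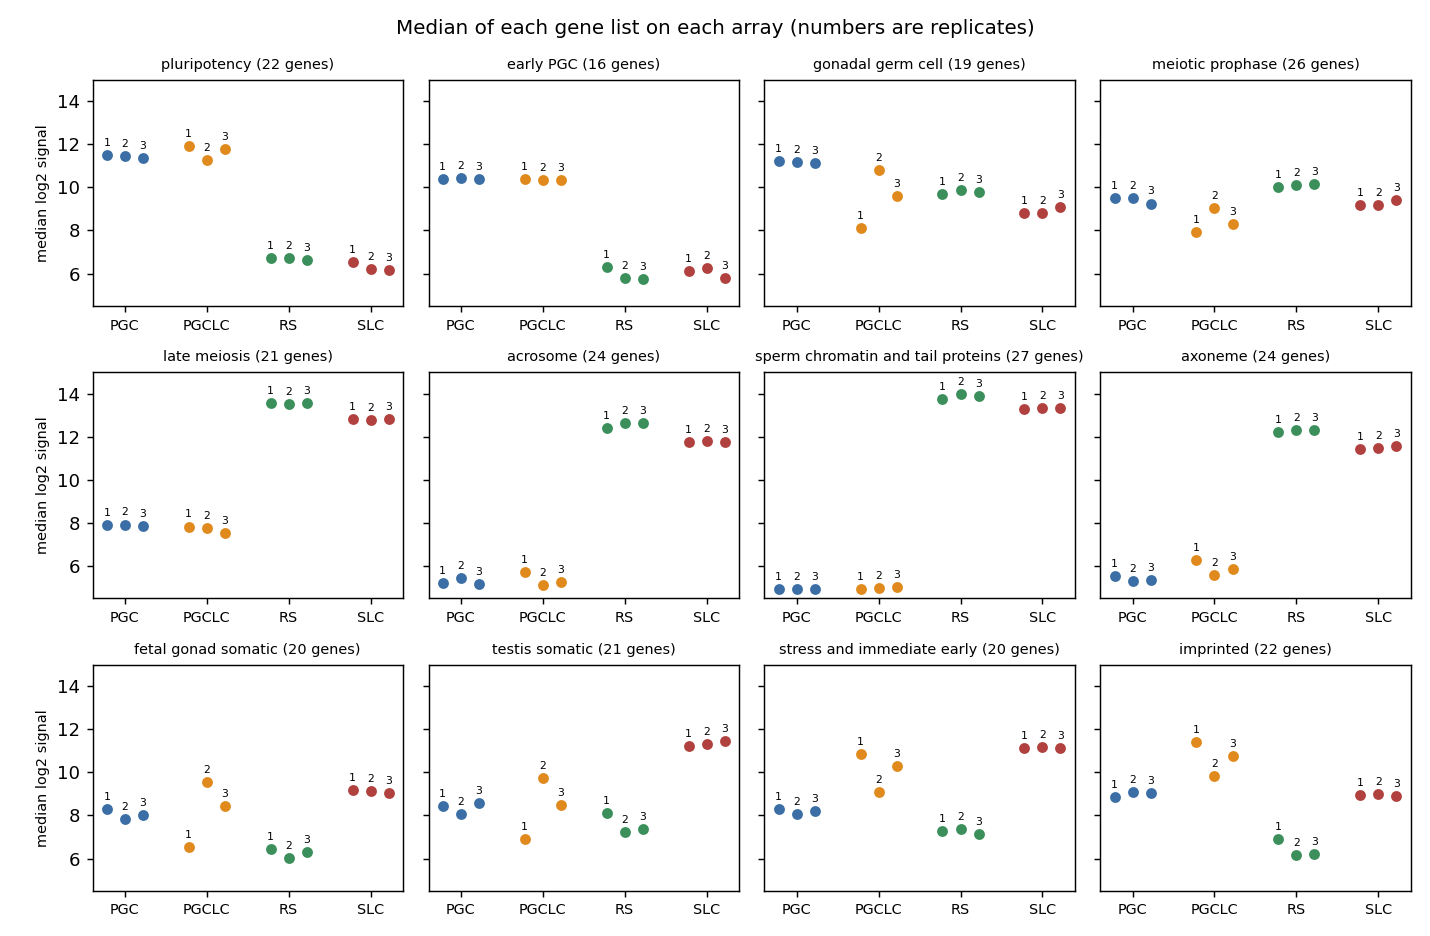
Median log2 signal of 12 gene lists on each array, with the replicate number above each point and the number of genes measured in each title. PGCLC replicate 1 is lowest of the PGCLC arrays for the fetal gonad somatic list and replicate 2 highest, and the spermatid lists of SLCs lie slightly below those of RS.

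SLCs were compared with RS to ask how spermatid-like cells differ from spermatids of the testis. Genes of testis somatic cells were higher in SLCs, with 17 of 21 rising, and so were stress and immediate early genes, with 16 of 20 rising. With an estimated correlation neither list passed limma camera (adjusted p = 0.104 and 0.307). That correlation takes in the PGCLC arrays and was 0.185 for testis somatic and 0.446 for stress in every contrast alike. It was not estimated from the SLC and RS arrays alone, so this result cannot decide whether the lists would pass on those arrays. By fry, which does not compare members with other genes, the unadjusted p was 1.46e-08 for testis somatic and 5.17e-07 for stress. Genes of meiosis, the acrosome, sperm chromatin, the sperm tail and the axoneme were a little lower as groups on the authors' scaling. Their list medians lay from -0.59 to -0.79 on the log2 scale, with few members past 2-fold. With an estimated correlation the meiotic prophase list did not pass limma camera (adjusted p = 0.47) and the other 4 did. Col1a1, a collagen of connective tissue, rose 81.2-fold, from 110 ± 49.5 units in RS to 8345 ± 368 in SLCs (log2 6.34, SE 0.30, limma adjusted p = 8.42e-09). Cyp11a1, which encodes the enzyme of the first step of steroid synthesis, rose at least 134-fold to 4115 ± 165, although only 1 of its 2 probe sets had this sign.

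In all, 3335 genes were higher and 472 lower in SLCs, and 465 of the higher genes were at least 16-fold higher. The largest fitted rises were those of Hp, which encodes the haemoglobin-binding protein haptoglobin, at least 411-fold from the floor to 12640 ± 447 (log2 8.68, SE 0.15, limma adjusted p = 5.57e-12), and Scd1, a fatty acid desaturase, at least 290-fold from 44.7 ± 27.6 to 14000 ± 728. Igfbp5, an IGF-binding protein, rose at least 235-fold to 7514 ± 801, the efflux pump gene Abcb1b at least 234-fold to 7201 ± 470.1, and the matrix gene Thbs1 at least 224-fold to 8554 ± 527. The largest falls were smaller. Dlgap3 fell 4.80-fold (286 ± 68.2 to 68.7 ± 49.2, adjusted p = 0.00158), Agtrap 4.02-fold (536 ± 86.5 to 173 ± 150, adjusted p = 0.0212), Tspan1 at least 3.91-fold, Fam131c 3.72-fold on the log2 scale and 3.37-fold by mean signals, and P2rx2, an ATP-gated channel gene, 3.63-fold and 3.26-fold.

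The spermatid lists moved together and by little. In the sperm chromatin and tail list 0 of 27 members passed 2-fold in limma, while 20 were lower at an adjusted p under 0.05 with no minimum fold and 21 at an unadjusted p under 0.05. Odf4, a tail protein gene, was at 7015 ± 848 in RS and 3700 ± 106 in SLCs (log2 -0.92, adjusted p = 6.73e-05), and Spem1 at 7234 ± 1167 and 4073 ± 50.2 (log2 -0.82). Of 24 acrosome genes 3 fell, namely Acr, a protease gene, 2.49-fold, Pick1 2.10-fold, and Acrbp. Of 21 late meiosis genes 2 fell, Pou5f2 2.70-fold and Ybx2, an mRNA-binding protein gene, 2.09-fold (16120 ± 378 to 7741 ± 889). Of 24 axoneme genes Foxj1, a regulator of ciliary genes, fell 2.13-fold. Dnaic1, at 1612 ± 75.5 in RS and 819 ± 69.3 in SLCs, did not pass (log2 -0.98, SE 0.488, limma adjusted p = 0.0991). Its SE takes in the PGCLC arrays, where it was at 275 ± 220. Of 26 meiotic prophase genes 0 passed 2-fold in limma and 14 were lower at an unadjusted p under 0.05, with Msh5 and Rec8, a meiotic cohesin gene, at log2 -0.96 and -0.92. These 5 lists had the same counts adjusted over the list alone.

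Of 22 spermatogonia genes 5 rose, the surface protein genes Cd9, 20.2-fold to 2319 ± 41.4, and Thy1, 11.8-fold to 711 ± 10.03, with Etv5, Foxo1 and Itga6, and Neurog3 and Sall4 fell. In the stress list Cdkn1a, a cell cycle inhibitor gene, rose 58.1-fold to 4674 ± 201 and Ier3 51.4-fold to 4900 ± 83.7. The fetal gonad somatic list, which shares members with the testis somatic list, had 14 of 20 rising and 0 falling. Lyz2, a macrophage gene, and Cdh5, an endothelial gene, rose 4.41-fold and 3.11-fold, and were the only 2 of 14 blood and endothelium genes called. Of 25 proliferation genes, Ccnd1 rose 3.16-fold and Plk1, a mitotic kinase gene, and Bub1b fell (Plk1 by 2.01-fold). Imprinted genes had 10 rises of 22, DNA methylation genes 3 of 12 (Dnmt3a, Tet2, Zbtb33), early PGC genes 3 of 16 (Ifitm1, Ifitm3, Prdm1) and sex-linked check genes 2 of 7 (Kdm5d, Uty). Among 15 epiblast and mesoderm genes Bmp4, Hoxb2 and Msx1 rose and Hand1 fell, among 22 pluripotency genes Tbx3 rose and Pou5f1, Sall4 and Zfp42 fell, and among 19 gonadal germ cell genes Tdrd9 fell. Adjusted over the list alone, the counts were the same except that 0 gonadal germ cell genes fell. X-linked genes were higher than the rest, with a median log2 change of 0.66 against -0.16 for autosomal genes and 43.2% of 472 genes called higher against 22.9%. That list had an adjusted p of 0.0564 by limma camera with an estimated correlation.

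By limma camera 12 of 19 lists passed. The late meiosis, acrosome, sperm chromatin and tail, and axoneme lists (medians -0.67, -0.75, -0.59 and -0.79) held with an estimated correlation, each at an adjusted p of 0.0422. The testis somatic list (median 3.70, preset adjusted p = 1.78e-05) had an adjusted p of 0.104 with an estimated correlation, the stress list (3.90) 0.307, the fetal gonad somatic list (3.26) 0.503, the imprinted list (0.93) 0.468, the meiotic prophase list (-0.73) 0.47, the gonadal germ cell list (-0.77) 0.679, the proliferation list (-0.48) 0.0564 and X-linked genes 0.0564. For the early PGC, DNA methylation, blood, spermatogonia and sex-linked lists the median was negative and the mean positive, and none of them passed. The 3' to 5' log2 ratio of Gapdh, a sign of RNA integrity, was 0.13 ± 0.12 in RS and -0.50 ± 0.06 in SLCs, beside all of these lists (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow, 0.2 after adjustment over 16 tests). The Actb ratio was 0.48 ± 0.02 in RS and 0.48 ± 0.14 in SLCs (difference 0.006, exact permutation p = 1). The hybridization spikes were at 11.25 ± 0.04 on the log2 scale in RS and lower in SLCs (difference -0.25, exact permutation p = 0.1, 0.2 adjusted). The labelling spikes went the other way, at 6.87 ± 0.16 in RS and 7.27 ± 0.28 in SLCs (difference 0.40, exact permutation p = 0.2, 0.356 adjusted). The median of all genes was -0.15, moving to -0.34 with quantile normalization and -0.76 with median centring. The share of calls that were higher moved with it from 87.6% to 54.3% and 29.4%, with 2289 and 5628 genes lower. Relative to the median of all genes, the testis somatic median was higher by 3.85.

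**Figure D3:**
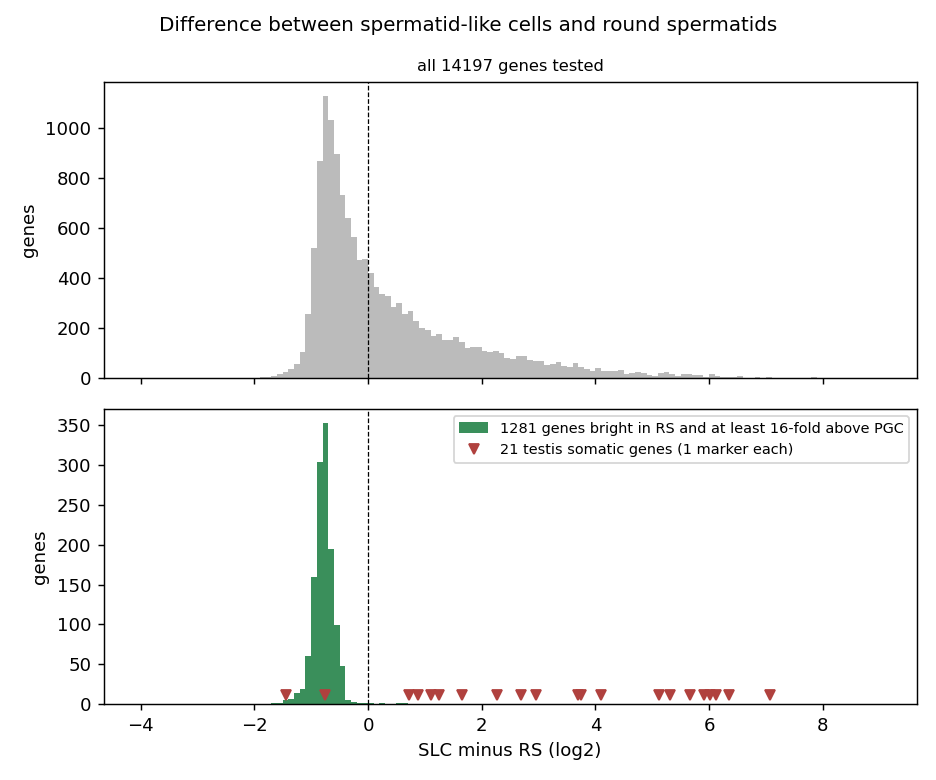
Histograms of the log2 difference between SLCs and RS in bins of 0.1, for all 14197 genes above and below for 1281 genes that are bright in RS and at least 16-fold above PGCs, with 21 testis somatic genes as triangles at an arbitrary height. The spermatid genes form a narrow peak with a median of -0.78, and 17 of the testis somatic genes were called higher.

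The change from PGCLC to SLC spans the stages made in vitro, in different cells and not in a followed culture. Spermatid genes rose, and most pluripotency genes fell, although that list had an adjusted p of 0.0583 by limma camera with an estimated correlation. All 24 axoneme genes, 26 of 27 sperm chromatin and tail genes, 21 of 24 acrosome genes and 16 of 21 late meiosis genes rose, while 20 of 22 pluripotency genes and 14 of 16 early PGC genes fell. Tnp1, a transition protein gene, rose at least 809-fold to 24960 ± 723 units (log2 9.66, SE 0.09, limma adjusted p = 1.03e-14). Sox2, a core pluripotency factor, fell at least 265-fold, from 8247 ± 1619 to the floor (log2 -8.05, SE 0.14, limma adjusted p = 2.91e-13).

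In total 4170 genes were higher and 3826 lower in SLCs than in PGCLCs, and 1172 and 135 of these differed by at least 16-fold. In the simulation this comparison also made more false calls than the adjusted p threshold allows, a mean of 58, so its adjusted p values may be too small. Besides Tnp1, the largest fitted rises were those of Spata4 (at least 714-fold, to 23950 ± 367), Tnp2 (at least 590-fold, to 18150 ± 531), the protamine gene Prm2 (at least 576-fold, to 24440 ± 389) and Crisp2 (at least 572-fold, to 17580 ± 582). The largest fitted falls were those of Dppa3 (at least 292-fold from 11400 ± 7811), Dppa5a (265-fold from 23200 ± 3911), Sox2, the cadherin gene Cdh1 (at least 241-fold from 8117 ± 2279) and Nanog (at least 205-fold). Adam3, a sperm surface gene, rose at least 316-fold, the acrosome genes Spink2 and Zpbp2 233-fold and at least 202-fold, and the axoneme genes Meig1 and Tekt4 313-fold (281-fold by mean signals) and at least 155-fold. Rhox6 fell at least 95.9-fold.

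Germ cell and meiotic lists went both ways. Of 19 gonadal germ cell genes 7 rose, including the piRNA pathway genes Gtsf1 (22.6-fold, to 12770 ± 126) and Mael (16.5-fold, to 14890 ± 620.2), and Dazl, Pnldc1, Stk31, Tdrd5 and Tex19.1 fell. Of 26 meiotic prophase genes 13 rose, including Syce3 20-fold, and Mnd1, a recombination gene, and Ythdc2 fell (Mnd1 at least 21.6-fold). Proliferation genes had 19 falls of 25 and 0 rises. Lower and higher counts were 12 and 4 of 22 spermatogonia genes, 7 and 1 of 12 DNA methylation genes, 11 and 0 of 22 imprinted genes, 8 and 2 of 14 blood and endothelium genes, 4 and 3 of 15 epiblast and mesoderm genes, 2 and 11 of 21 testis somatic genes, 2 and 8 of 20 fetal gonad somatic genes, 0 and 6 of 20 stress genes, and 0 and 1 of 7 sex-linked genes. Adjusted over the list alone, all counts were the same except 6 higher fetal gonad somatic genes and 1 lower sex-linked gene. X-linked genes had a median of -0.63 against -0.06 (adjusted p = 0.213 by limma camera with an estimated correlation).

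Of 12 lists that passed limma camera, 6 held with an estimated correlation, namely axoneme (adjusted p = 0.00223), sperm chromatin and tail (0.00266), acrosome (0.00502), late meiosis (0.00591), early PGC (0.00739) and proliferation (0.00767). With an estimated correlation the adjusted p was 0.0583 for pluripotency (median -4.85), 0.0652 for DNA methylation, 0.1 for spermatogonia, 0.362 for testis somatic, 0.402 for imprinted and 0.213 for X-linked genes. Beside these lists, the Gapdh ratio was -0.34 ± 0.05 in PGCLCs and -0.50 ± 0.06 in SLCs (difference -0.16), the labelling spikes 8.63 ± 0.30 and 7.27 ± 0.28 (-1.36) and the hybridization spikes 11.60 ± 0.16 in PGCLCs with a difference of -0.60. Each had a two-sided exact permutation p of 0.1, the smallest possible, and 0.2 after adjustment, while the Actb ratio differed by 0.01 (exact permutation p = 1). Requiring a change beyond 2-fold by limma treat left 2363 genes lower.

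RS and PGCs give the same span of stages in the animal. The same lists led, with 26 of 27 sperm chromatin and tail genes, 22 of 24 axoneme genes, 21 of 24 acrosome genes and 18 of 21 late meiosis genes higher in RS. Pluripotency and early PGC genes were lower, with 16 of 22 and 14 of 16 falling, and with an estimated correlation the early PGC list passed limma camera and the pluripotency list did not (adjusted p = 0.00977 and 0.192). Spata4, a testis gene, rose at least 1050-fold, from the floor to 32170 ± 921 units (log2 10.03, SE 0.11, limma adjusted p = 7.41e-15). Dppa3 fell at least 520-fold from 21480 ± 585 (log2 -9.02, SE 0.51, limma adjusted p = 5.8e-09).

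Counts were 4467 higher and 5277 lower, with 1470 and 525 of them at least 16-fold apart. Tnp1 rose at least 1010-fold, Prm2 at least 924-fold to 29530 ± 1590, Smcp, a sperm mitochondrial sheath gene, at least 836-fold to 25700 ± 130, and Tnp2 at least 793-fold. After Dppa3 the largest fitted falls were those of Hbb-y, at least 379-fold from 11650 ± 408, Dppa5a, 222-fold, L1td1, at least 221-fold from 6970 ± 428, and Lrrfip1, at least 212-fold from 7488 ± 23.6. In the lists, Crisp2 rose at least 726-fold, the glycolytic gene Pgk2 at least 586-fold to 18040 ± 866, Spink2 at least 402-fold, Zpbp2 at least 334-fold, and the tektin genes Tekt4 and Tekt1 at least 268-fold and at least 244-fold. Prdm14, a PGC specification factor, fell 55.6-fold. Hook1, a cytoplasmic linker gene of the sperm chromatin and tail list, fell in both stage comparisons.

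Gonadal germ cell genes split into 5 higher, Gtsf1 (24.0-fold), Mael, Taf7l, Tdrd1 and Tdrd9, and 8 lower, including Tex19.1 18.7-fold. Of 26 meiotic prophase genes 12 rose, including Syce3 11.9-fold, and Hormad2, Tex11, Tex12, Ythdc2 and Mnd1 fell (Mnd1 at least 47.8-fold). Higher and lower counts were 1 and 15 of 25 proliferation genes, 4 and 14 of 22 spermatogonia genes, 2 and 7 of 12 DNA methylation genes, 2 and 14 of 22 imprinted genes, 3 and 12 of 20 stress genes, 1 and 12 of 20 fetal gonad somatic genes, 2 and 9 of 21 testis somatic genes, 5 and 5 of 14 blood and endothelium genes, 4 and 7 of 15 epiblast and mesoderm genes, and 1 and 4 of 7 sex-linked genes. Adjusted over the list alone, the counts were the same except 23 higher axoneme genes and 7 lower gonadal germ cell genes. X-linked genes were lower than the rest, with a median of -1.37 against -0.20 and 56.4% called lower against 36.6% of autosomal genes. With an estimated correlation the adjusted p of X-linked genes by limma camera was 0.101.

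Limma camera passed 9 lists, of which 5 held with an estimated correlation, axoneme (adjusted p = 0.00264), sperm chromatin and tail (0.00376), late meiosis and acrosome (both 0.00438) and early PGC (0.00977). With an estimated correlation the adjusted p was 0.192 for pluripotency (median -4.54), 0.073 for proliferation, 0.552 for imprinted and 0.101 for X-linked genes. For the gonadal germ cell list the median of -0.40 was negative and the camera sign positive (adjusted p = 0.828). The Gapdh ratio of 0.13 ± 0.12 in RS, against -0.41 ± 0.04 in PGCs, lay beside these lists (two-sided exact permutation p = 0.1, the smallest possible, 0.2 after adjustment), as did the labelling spikes (difference -1.77) and hybridization spikes (-0.29) at the same exact permutation p. The Actb ratio differed by -0.09 (exact permutation p = 0.3). The median of all genes moved from -0.22 to -0.03 with quantile normalization and to 0.24 with median centring.

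The stage changes in vitro and in vivo share no array, and most genes called in vivo were called the same way in vitro. In both, 3447 genes were higher, where 1312 would be shared by independent lists, and 3294 were lower, where 1422 would be. These are 77.2% of the genes higher and 62.4% of the genes lower in vivo, and 213 genes were called in opposite directions. Across genes Pearson's r was 0.878 and Spearman's rho 0.828. For the differences between in vitro and in vivo cells, 744 genes were higher in vitro at both stages against 342.5 for independent lists, and 10 were lower in both against 7.55, with an r of 0.335 and a rho of 0.243 across genes. These counts depended on the scaling between arrays, with 98 lower in both by quantile normalization and 471 higher and 340 lower by median centring. All contrasts came from a single fit with a shared variance per gene. A gene of small variance is called more easily in each, so the numbers for independent lists are only a rough reference.

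**Figure D4:**
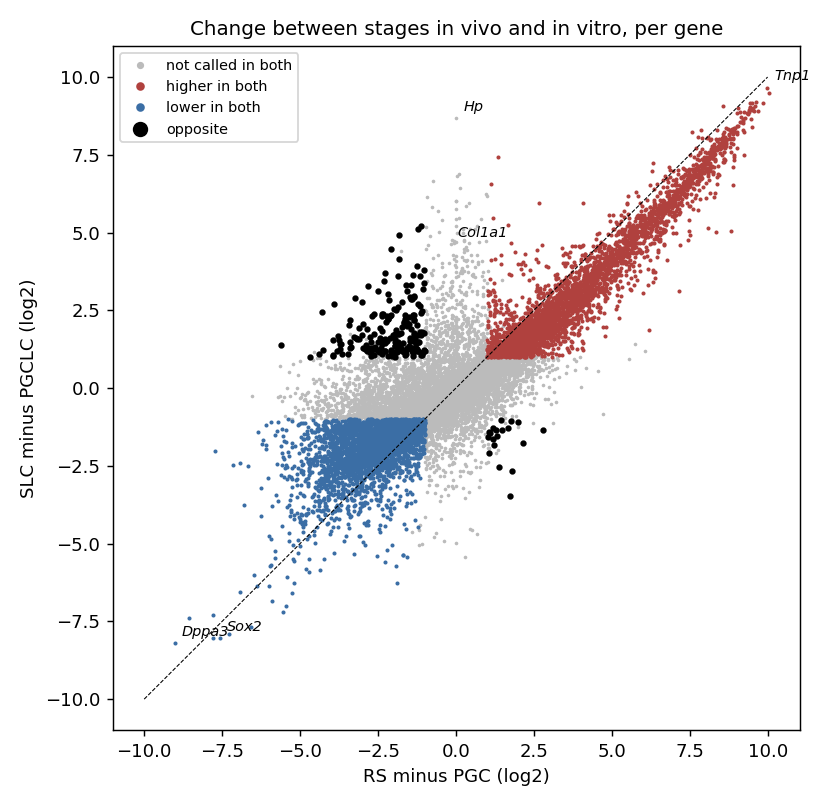
Log2 change of each gene from PGC to RS on the x axis and from PGCLC to SLC on the y axis, with the line of equal change dashed. Genes called higher in both (3447) and lower in both (3294) lie along the line, and 213 genes were called in opposite directions.

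The interaction asks which genes changed by different amounts between the stages in vitro and in vivo. Hp had the largest fitted difference, a log2 of 8.68 (SE 0.21, limma adjusted p = 4.03e-10), and as it was at the floor on all PGC, PGCLC and RS arrays this is no bound on the true difference. The folds of the other genes are fitted values as well. Lox, a collagen cross-linking enzyme gene, followed at 166-fold, from 95.6 ± 54.6 in PGCLCs to 8283 ± 77.2 in SLCs beside 86.2 ± 16.9 in PGCs and 56.3 ± 30.3 in RS. The purine enzyme gene Gda was at 134-fold, Ly6e at 127-fold and the growth factor gene Ereg at 111-fold. In the other direction were Cldn4 (52.9-fold), the keratin gene Krt8 (41.5-fold), Acta1 (37.0-fold), Fabp7 (33.5-fold) and the neurofilament gene Nefl (31.5-fold), each brighter in PGCLCs than in the other groups.

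The change was more positive in vitro for 2936 genes and more negative for 1571. Testis somatic genes had 13 of 21 more positive (14 adjusted over the list alone) and 0 more negative, fetal gonad somatic genes 13 and 1 of 20, and stress genes 12 and 3 of 20. Of 24 axoneme genes 11 were more negative, of 24 acrosome genes 5, of 27 sperm chromatin and tail genes 2, of 21 late meiosis genes 3 and of 22 pluripotency genes 7, with 0 more positive in each. Limma camera passed 10 lists and 0 held with an estimated correlation, the lowest adjusted p being 0.0578 for the axoneme list. Without probe sets ending in _x_at and _s_at the call of Ly6e was lost, and with median centring the median of all genes moved from -0.05 to -0.44 and the share of more positive calls from 65.1% to 38.2%, with 3535 more negative.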

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

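The tests on differences among the PGCLC arrays and on the spermatid and testis somatic genes of SLCs were chosen only after the result was seen, and those on X-linked genes and on other splits of the arrays were set before, except matching X-linked genes on levels other than RS and adding a difference to them, chosen after.

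PGCLC replicates 2 and 3 lay between PGCLC replicate 1 and PGCs for genes such as Ddx4 and Zic1. Fitted as a mix of the mean PGC signal and replicate 1 over 182 genes, replicate 2 took a share of 91.2% of the PGC mean. The median residual was 0.263 on the log2 scale. Replicate 2 was no plain mix of them, as 119 genes were at least 2-fold higher in it than in PGCLC replicate 1 and every PGC array. In the same fit replicate 3 took 31.3% of the PGC mean and left 0.098, beside 0.096 between PGC arrays. A share of RNA like that of the PGC samples thus cannot be excluded for replicate 3. An exchange of replicate 2 with a PGC array is argued against by 60 genes dim in PGCs and high in PGCLC replicate 1. In replicate 2 their median lay 1.75 above the PGC mean on the log2 scale. The fetal gonad somatic list had a median there 1.39 above PGCs and 2.62 above PGCLC replicate 1. That sets replicate 2 apart from the PGC arrays measured. It cannot decide about RNA of a fetal gonad with a larger somatic share, which would also raise these genes. Over 73 genes at least 8-fold apart between replicates 1 and 2, replicate 3 could be a mix of 2 RNA sources, since a common linear share of 35.8% of replicate 2 left a median residual of 0.072 on the log2 scale, below the 0.096 between PGC arrays. A state of all cells part-way between those of replicates 1 and 2 left 0.125 and cannot be told apart from it, because that residual lay under the bound set for excluding it. In simulated mixes with 20%, 50% and 80% of replicate 2, the part-way fit left 0.117, 0.124 and 0.143. The linear share left 0.055, 0.061 and 0.065 there. A part-way residual near 0.125 thus also comes from a true mix. Data of a part-way state were not simulated. A difference in maturity of the cultures stays open as an untested biological explanation. The FACS gate was not given, so whether it removed gonad or blood cells is not known.

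In SLCs the spermatid genes were lower and the testis somatic genes higher than in RS. Of 1281 genes bright in RS and at least 16-fold above PGCs, 99.6% were lower in SLCs. Their median was -0.78, or 58.1% of the RS signal, with an SD over genes of 0.19. The medians of the 5 germ cell lists from meiosis to the sperm tail, over members bright in RS, lay within 0.22 of each other. Without members at the top of the array range the span was 0.093, and 76 of the 1281 genes at that top moved less, with a median of -0.50. For these bright members this argues against SLCs at another step of spermatogenesis as the cause, since that would spread the lists. Members dim in RS, which an earlier step could raise, were left out here, although 0 measured members of the 5 lists were called higher. A nearby step need not spread the lists and cannot be excluded. RNA of somatic cells in the SLC arrays is a candidate explanation that needs this even 0.22 spread and abundant somatic transcripts, which were at 25060 ± 367 (Sparc), 21950 ± 380.4 (Col1a2) and 20400 ± 771 (Col3a1) beside 719 ± 53.7, 343 ± 51.6 and 294 ± 37.5 in RS, although Cyp17a1 and Rhox5 were not higher, 9 of the 21 list genes are in another list and 14 are above the filter level in RS. A single scaling factor on the SLC arrays is argued against for the higher testis somatic genes, whose median was 3.85 above that of all genes, but for the lower spermatid genes it cannot be told apart, as 1945 genes bright in both RS and PGCs were 0.397 higher than the spermatid genes, within the bound of 0.4 set for excluding it. A biological difference between cells made in vitro and in the testis stays open and untested. The FACS gate was not given, so whether it removed somatic cells is not known.

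X-linked genes were higher than autosomal genes in SLCs against RS. Against autosomal genes of like RS and PGC level, 471 X-linked genes had a median excess of 0.067 on the log2 scale (95% bootstrap interval -0.003 to 0.146) beside 0.82 without matching. Matched on SLC and PGC level instead, the excess was 0.606, and on PGC and PGCLC level 0.4. With 0.82 added to X-linked genes in SLCs the excess matched on RS and PGC level was 0.885, and with 0.82 taken off in RS it was 0.669. RNA of somatic cells and a difference of X-linked genes themselves cannot be told apart, because the RS level is a term of the difference compared and the excess depends on which level is matched.

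Interaction tests showed differences between the stage changes in vitro and in vivo for 2936 genes that were more positive in vitro and 1571 that were more negative. List medians of the interaction that passed limma camera were -0.88 for pluripotency, 3.10 for fetal gonad somatic, -0.36 for late meiosis, -0.75 for acrosome, -0.69 for sperm chromatin and tail, -0.85 for axoneme, 2.39 for testis somatic, -0.39 for proliferation, 1.84 for stress and immediate early and 0.57 for X-linked genes, and 0 of the 10 passed with an estimated correlation. Of 100 random regroupings of the arrays within each stage, the real one included, 4 called as many genes as the real 4507 and the highest of the others called 5549. All 4 kept the SLC arrays together, as 10 of the 100 did, and the highest that parted them called 0. A split that parts the SLC arrays also mixes them with RS arrays, which raises the variance of the fit. A count near 0 was thus largely set in advance for such splits. The share of 4 in 100 does not settle whether the interaction itself is due to chance. For the other contrasts, 10 splits of 6 arrays are too few for a share under 0.05. The real split called 1685 genes for PGCLC minus PGC, 3807 for SLC minus RS, 7996 for SLC minus PGCLC and 9744 for RS minus PGC, was the 1 split of each 10 with as many, and the highest other splits called 4, 1, 0 and 0.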

How the results depend on the processing

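Keeping only PGCLC replicate 1 and raising the SLC arrays were chosen after the result was seen, and the other 28 settings were planned. Of 272 counts of called or shared genes under these settings, 228 stayed within 1.5 times the value reported and 44 moved, and none of the named genes turned direction. Named genes kept their side of the threshold in 568 of 681 values for PGCLC minus PGC, 630 of 683 for SLC minus RS, 459 of 459 for SLC minus PGCLC, 461 of 461 for RS minus PGC and 285 of 286 for the interaction. In every setting alike, 0 of 30 named genes for PGCLC minus PGC kept their side, and 11 of 30 for SLC minus RS. The numbers were 20 of 20 for SLC minus PGCLC, 21 of 21 for RS minus PGC and 9 of 10 for the interaction. Of 1640 list counts 226 moved, and of 52 camera calls 15 held with an estimated correlation. The replicate numbers did not pair the arrays (18 same-number pairs, correlation of residuals -0.017 to 0.133, 1 over 0.1), and with the replicate number as a block the higher and lower counts were 1456 and 224 for PGCLC minus PGC, 3338 and 467 for SLC minus RS, 4165 and 3831 for SLC minus PGCLC, 4470 and 5272 for RS minus PGC and 2929 and 1578 for the interaction. For PGCLC minus PGC, the lower count was 375 with quantile normalization, 639 with median centring and 483 with array weights, the higher count 862 with the stricter filter, and higher and lower counts were 168 and 7 with only the 2 groups fitted, 2366 and 1916 by adjusted p alone, 52 and 1 by limma treat, and 2294 and 1225 with only PGCLC replicate 1. Leaving out each array in turn gave 958 (without PGCLC replicate 3) to 2122 (without PGCLC replicate 2) higher and 58 (without PGCLC replicate 1) to 757 (without PGCLC replicate 2) lower. For SLC minus RS, the lower count was 2289 with quantile normalization, 5628 with median centring, 279 with no floor, 272 with a pseudocount, 245 with the stricter filter, 4472 by adjusted p alone and 6 by treat, and with the SLC arrays raised 5450 were higher and 7 lower. Treat left 2363 lower for SLC minus PGCLC. For the interaction the lower count was 3535 with median centring, 964 with the stricter filter and 3101 by adjusted p alone, and higher and lower counts were 1515 and 118 by treat and 5367 and 270 with the SLC arrays raised. Genes lower in vitro at both stages were 98 with quantile normalization, 340 with median centring, 1 with the floor at the median, 5 with no floor, 4 with a pseudocount, 6 with the stricter filter and 46 with only PGCLC replicate 1, and genes higher at both were 471 with median centring. Stricter filters test fewer genes, and adjusted p alone and treat change the fold that is asked for. For the other settings the cause was not tested. Changes of genes near the floor are limited by signal over background, and detection calls were not available.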

Other observations

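The overlaps with gene lists given here were chosen after the result was seen.

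Stress and immediate early genes made up part of the set that was higher in vitro at both stages. Of 20 measured members, 15 rose both in PGCLCs against PGCs and in SLCs against RS, within 744 of 14197 genes overall. The immediate early gene Fos was at 2580 units in PGCs and 12070 in PGCLCs, and at 668 in RS and 12480 in SLCs. Egr1 was at 3292 and 10000, and at 539 and 17150, and Jun at 336.5 and 2721, and at 213.5 and 4059. The heat shock gene Hspb1 was at 470.1 and 8809, and at 823 and 4959. In PGCLCs minus PGCs the stress list had 18 rises, and these calls share the limit that a fit of the 6 arrays alone kept 171 of 1685 calls.

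Fewer members of the imprinted and testis somatic lists were higher in vitro at both stages. Of 22 imprinted genes 7 rose in both, among them Meg3, a maternally expressed long RNA, at 905 units in PGCs, 4378 in PGCLCs, 146 in RS and 6854 in SLCs, and Grb10, an adaptor of growth factor signalling, at 875, 4855, 444 and 2475. Of 21 testis somatic genes 7 rose in both, among them Vim, an intermediate filament gene of mesenchymal cells, at 2196, 7397, 311 and 12330, and Sparc, a matrix gene, at 2180, 5233, 719 and 25060. For the whole testis somatic list the PGCLC arrays lay on both sides of PGCs. Its median log2 signal was 6.89 on PGCLC replicate 1 and 9.76 on replicate 2, beside 8.09 to 8.58 in PGCs. No member of the meiotic prophase, late meiosis, acrosome, sperm chromatin and tail, or axoneme lists was called the same way in both by limma. The gonadal germ cell gene Tdrd9 was the single list member lower in both.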
